A study of Mus musculus with 2 samples.

How the data were processed

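DNase-seq libraries of left cerebral cortex came from 2 female B6CASTF1/J mice aged 36 days, 1 library per animal, per the labels, which give the animals different numbers under a shared donor entry. They form 1 group, numbered replicate 1 and replicate 2 as in the labels, and no second group exists for a comparison. The p-values given for gene lists therefore run over genes or random lists and describe these libraries, not a population of mice.

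For each library the authors deposited, per the deposited read-me text, peak calls, footprint calls and false discovery rates of the cut rate, all made per library on mm10. The aligner and the peak caller are not given in the sources used here. Each library has 2 peak lists. Every peak of the shorter list holds a position under a rate of 0.001 in the deposited rate file and every peak of the longer list a position under 0.05, and the shorter list is called peaks and the longer one the longer list. The deposited peak height is a signal value, and it is used as the authors' own value for each peak. All heights below 1 were whole multiples (tolerance 0.05) of a step of 0.00608 in replicate 1 and 0.00561 in replicate 2, as whole numbers of cuts divided by a factor per library would be, but what the factor is was not stated. Heights were therefore ranked or filtered within a list, and regions were compared between lists as log2 ratios centred on their median. The median ratio itself and the mean height of the mice, used to rank and match peaks and for summed height, carry the unstated factors. The deposited rates are false discovery rates (FDR) of the cut rate for runs of positions and list positions under 0.05 only, 39.7 Mb in replicate 1 and 42.7 Mb in replicate 2. The deposited footprint score is the same number in every entry, so only footprint positions were used. Depth in reads is unknown, and intervals on shares cover counting error only.

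Coordinates are on mm10 and 1-based. The GRCm38 sequence and the GENCODE M21 annotation (55413 genes, 21938 of them protein-coding) were used for position, gene and motif calls. As a check of the match between sequence and annotation, 21823 of 21828 annotated start codons read ATG. Peaks of the mice were called shared when they overlapped by at least 1 bp. The random expectation came from 100 placements of each list on its own chromosomes outside assembly gaps (bedtools 2.31.1). A peak was a promoter peak when its centre lay within 1 kb of any annotated transcription start, and otherwise exonic, intronic or intergenic in that order. A gene had a promoter peak when a region called in both mice came within 1 kb of one of its starts, so a gene can share its peak with a neighbour, as 12 of 138 promoter-positive list genes did. Heights given for genes are those of the highest such peak in replicate 1 and replicate 2.

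Gene lists were fixed before the data were examined, as were the motifs, the tests of the main comparisons and most of the alternative settings. The tests of height ratios at CTCF matches and gene lists, motif content, CpG content, gene types, peaks of 1 mouse only and male DNA were chosen later. There were 20 lists, 19 of named genes with 303 entries in all and 1 of olfactory receptor genes. They cover cortical excitatory neurons, interneurons, astrocytes, the oligodendrocyte lineage, microglia, vessels and meninges, choroid plexus and ependyma, blood, striatum, other brain regions, liver, skeletal muscle, pancreas and gut, Hox genes, immediate early genes, synaptic genes, housekeeping genes, imprinted genes and X inactivation. The density of a gene is the number of merged regions called in both mice per 10 kb of gene body and 10 kb flanks. Its mean over protein-coding genes was 0.487. Each list was set against 10000 random lists of protein-coding genes matched on deciles of gene length (density) or on quintiles of promoter CpG content (promoter peaks), two-sided, with Benjamini-Hochberg adjustment over the 20 lists. Genes were drawn without replacement within each stratum, so this is a permutation of list membership among matched genes, and its values are given as permutation p. The smallest p these random lists can give is 2e-04 before adjustment, and several lists reached it. Pooled cortical lists were compared with pooled lists of other organs and of other brain regions by two-sided permutation tests over genes with 100000 resamples, whose smallest p is 1e-05.

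The genes named in the text follow a rule fixed beforehand. From each list it takes the 3 members with the highest mean promoter peak and up to 3 members without a promoter peak in both mice, in alphabetical order. It adds the 10 protein-coding genes with the most regions, the 10 with the highest promoter peak, and the 5 regions furthest to each side of the median height ratio among regions above the median height. Any other gene is named as chosen after its values were seen. Some genes that the rule takes are not reported here.

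For footprints, 26 consensus motifs were searched on both strands inside peaks. The share of matches whose central base lay in a footprint was set beside the share of positions 50 bp to each side inside the same peak, with Wilson 95% intervals. The CTCF consensus was CCASYAGRKGGC in IUPAC letters. Footprints placed at random within the peaks of their own library (100 placements) gave the expectation for footprints shared by the mice.

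Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, samtools 1.23.1 and, for copies of Y sequence, BLAST+ 2.17.0. The overlap count, the list tests, the motif search and the matched height ratio were tested on data with known answers, simulated or altered from the real data. Known shares of the 69208 peaks of replicate 1 were moved off their own list, and the moved share was recovered without error. This checks the counting only, not the overlap between mice. The random-list test called 4.5% of simulated lists with no shift and 92.0% with a shift of 1 genome mean (21938 genes), and the permutation test of pooled lists called 3.5% and 97.0% of 200 simulated comparisons. All 5200 planted motifs were found, and a planted height ratio was recovered to within 0.03 log2 units (40000 peaks).

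Alternative settings fixed at the same time were a reciprocal overlap of 50%, peaks above the median height of each list, the longer lists, start-site windows of 500 bp and 2 kb, starts of protein-coding genes only, 50 kb flanks, regions outside promoters, summed height, either library alone, footprints in shared peaks, a 1 bp overlap of motif and footprint, and positions under a rate of 0.001. Added after the data were seen were overlaps with the longer list or with the listed positions of the other mouse, promoter peaks in the longer lists, and the same alternatives for each list alone. A setting with high-scoring footprints only could not be run because the score is constant. The deposited read-me texts hold no measurements and were used for file contents only. Alleles of the parental strains were not analysed here.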

Results

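DNase-seq marks the parts of the genome that the nuclease DNase I can reach, which are mostly promoters, enhancers and other sites bound by regulatory proteins. It was applied to left cerebral cortex of 2 female mice aged 36 days, an F1 cross of the B6 and CAST strains (B6CASTF1/J). Each animal gave 1 library, called replicate 1 and replicate 2, and both belong to 1 group, so no condition was compared with another. The deposited lists held 69208 peaks in replicate 1 and 69128 in replicate 2, which covered 15.1 and 16.2 Mb of the mm10 genome. The median peak was 200 bp wide in replicate 1 and 202 bp in replicate 2. Its height was worth about 193 and 162 of the smallest steps found in each library's height values. Read totals are not given in the sources used here, so the depth of the libraries is unknown. The question the design allows is which regions were accessible in this tissue and how alike the animals were.

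Most accessible regions were found in both mice. Of the peaks of replicate 1, 51642 (74.6%) overlapped a peak of replicate 2, and 51355 (74.3%) of the peaks of replicate 2 overlapped one of replicate 1. The mean was 74.5% ± 0.233 (SD over the 2 directions of 1 comparison, not a spread between mice). Lists placed at random on the same chromosomes overlapped on average 1.21% of the time in either direction, and at most 1.34% in 100 placements. High peaks were shared more often than low ones. Of the peaks above the median height of their own list, 94.4% in replicate 1 and 95.2% in replicate 2 met a peak of the other mouse. After peaks were merged, 48886 regions held a peak in both mice, 17179 in replicate 1 alone and 17358 in replicate 2 alone.

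Peak heights followed each other closely between the animals. Across the 45612 regions with exactly 1 peak per mouse, Spearman's rho of the heights was 0.901 (95% bootstrap interval over regions 0.899 to 0.903). The heights of replicate 2 were lower by a median factor of 0.744, and after centring on that median the log2 ratio had an SD of 0.48, with 95.6% of regions within 1 unit. The SD was 0.36 at promoters and 0.54 elsewhere, against 0.14 that counting error would give for the median region if each step were 1 cut. Heights are the authors' own values with a normalization that is not stated, and regions are not replicates, so these values describe this pair of libraries. Among regions above the median height, the largest ratios in favour of replicate 2 lay 35520 bp from Pak3 (X:143483001-143483140, intergenic, centred log2 ratio 2.36), in an exon of Gm11168 (9:3006800-3006920, 2.10) and in an intron of Gm10722 (9:3002037-3002240, 1.61). Next came an intergenic region 372451 bp from Csmd1 (8:15520031-15520140, 1.44) and a promoter region of Ptprt (2:161799936-161800240, 1.37). The largest in favour of replicate 1 lay near Fam169b (7:68369771-68369940, -1.91), Hmgb2 (8:57503741-57503920, -1.85, with a CTCF match), Arl14 (3:69238561-69238740, -1.83) and Mctp2 (7:72362801-72363000, -1.75) and in an intron of Upp2 (2:58680901-58681080, -1.75). With 1 library per animal and no second group, none of these differences can be tested. The regions at Gm11168 and Gm10722 lie close together on chromosome 9. No filter for repeat sequence or mappability was applied to the deposited peaks, so the gene names here mark position only.

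Promoters were the most enriched class of position. Peak centres lay within 1 kb of an annotated transcription start site in 39.3% ± 1.29 of peaks (SD, n = 2 mice), 6.17-fold above the 6.37% of random placements. Exons outside promoters held 4.84% ± 0.511, against 3.40% at random. Introns held 29.0% ± 0.872 against 40.2%, and intergenic sequence 26.9% ± 0.928 against 49.99%. All 4 differences from random exceeded both the spread between the mice and the range of the placements. Repeat sequence made up 7.35% of the bases in peaks of replicate 1 and 7.18% in replicate 2, against 36.4% of the genome.

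**Figure D1:**
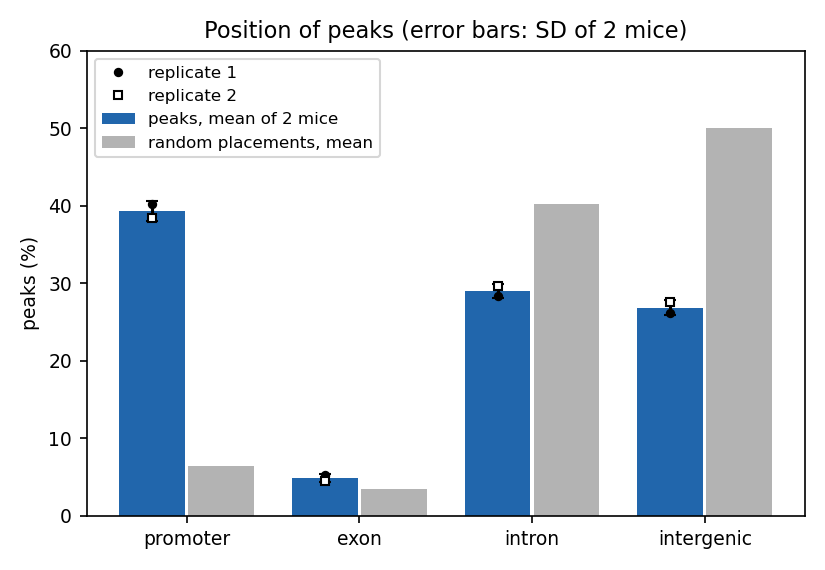
Share of peaks (%, vertical axis) whose centre lay in each class of position, as the mean of 2 mice with SD, beside the mean of 100 random placements per mouse. Promoters held 39.3% of peaks against 6.37% at random, and intergenic sequence 26.9% against 49.99%.

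Genes of cortical excitatory neurons stood in densely accessible neighbourhoods. Their 15 listed members carried a mean of 0.991 regions called in both mice per 10 kb of gene body and 10 kb flanks, 2.36-fold above random protein-coding lists of the same lengths (adjusted permutation p = 0.0016 over 20 lists). All 15 had a promoter peak in both mice (adjusted permutation p = 0.0064). The highest stood at Tle4, a corepressor of deep-layer projection neurons (19:14448150-14598051, heights 10.5 in replicate 1 and 8.52 in replicate 2). Camk2a, a kinase of excitatory synapses (18:60925618-60988152), had 4.04 and 2.75. The density call was lost with 50 kb flanks (0.554 regions per 10 kb, 1.58-fold random, adjusted permutation p = 0.0593). It held in either library alone, where all peaks of that library count and the densities were 1.73 and 1.92.

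Promoters of interneuron genes were open less often than those of random lists. Of 14 interneuron genes, 6 had a promoter peak in both mice (adjusted permutation p = 0.0147, random lists matched on CpG content). They included Adarb2 (1.53 and 1.18) and the calcium-binding protein gene Pvalb (1.64 and 0.701). Dlx1 (peak in replicate 1 only), Dlx2 and Dlx6, homeobox genes of developing interneurons, had none called in both mice. Of 12 astrocyte genes 9 had one in both mice (adjusted permutation p = 0.243), with the intermediate filament gene Gfap (3.61 and 1.71), the glutamate transporter gene Slc1a2 (2.76 and 1.74) and Sox9 (2.71 and 1.78) highest, and Aqp4 and S100b (peak in replicate 2 only) without. At Fgfr3, a growth factor receptor gene, each mouse had a promoter peak but the peaks do not overlap. Of 16 oligodendrocyte lineage genes 5 had one in both mice (adjusted permutation p = 0.0571), among them the growth factor receptor gene Pdgfra (3.37 and 1.75), the myelin regulator Myrf (2.68 and 1.27) and Olig1 (1.77 and 1.41), but not Cldn11 or Cspg4 (each with a peak in replicate 1 only) or Ermn. Densities of the 3 lists were 0.304, 0.577 and 0.563 regions per 10 kb, none of them past the threshold (adjusted permutation p = 0.173, 0.566 and 0.781). Without replicate 2 the counts were 8 interneuron (adjusted permutation p = 0.136) and 8 oligodendrocyte promoters, and the interneuron and astrocyte densities 0.804 (1.07-fold random, from below it) and 0.901, while without replicate 1 there were 11 astrocyte (adjusted p = 0.0274) and 5 oligodendrocyte promoters, the latter then below random (adjusted p = 0.0404). The longer lists had 12 astrocyte (adjusted permutation p = 0.0056) and 8 interneuron promoters (adjusted p = 0.0664), oligodendrocyte density stood above random without promoter peaks (0.395, adjusted p = 0.0353), and above the median height interneuron density stood below it (0.136, adjusted p = 0.0416), with 1 interneuron and 5 astrocyte promoters open.

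Markers of rarer or neighbouring cells were open in part. Of 14 microglial genes, 3 had a promoter peak in both mice, among them the transcription factor gene Irf8 (3.23 and 1.81) and the complement gene C1qc (1.58 and 0.999). Aif1 (peak in replicate 1 only), C1qa and C1qb had none called in both mice. Of 16 vascular and meningeal genes 6 had one in both mice, including the collagen gene Col1a1 (3.49 and 2.59), Foxc1 (1.65 and 1.36) and the endothelial factor Erg (1.25 and 0.735), but not Abcc9 (peak in replicate 2 only), Cdh5 or the tight junction gene Cldn5. Of 14 blood genes 1 had a peak, and Alas2 and Cd3e were among those with none. None of the 3 counts passed the threshold (adjusted permutation p = 0.243, 0.243 and 0.447), nor did the densities of 0.415, 0.339 and 0.317 regions per 10 kb (adjusted p = 0.659, 0.665 and 0.262). Of 10 genes of choroid plexus and ependyma 2 had a promoter peak (adjusted permutation p = 0.0255), the cilia regulator Foxj1 (9.76 and 5.10) and Enkur (6.51 and 4.89), whose peak is shared with Thnsl1, while Aqp1, Clic6 and Folr1 had none, and their density of 0.172 lay below random lists (adjusted p = 0.01). Without replicate 2 there were 5 microglial promoters, in the longer lists 7 microglial and 12 vascular promoters were open, and the 3 choroid plexus promoters (0.506-fold random) were no longer past the threshold (adjusted permutation p = 0.0575). Above the median height 2 vascular promoters were open (adjusted permutation p = 0.00514) and the choroid plexus call was lost (0.421-fold random, adjusted p = 0.0916), as was its density call, at 0.316-fold random, with 50 kb flanks (0.623-fold, adjusted p = 0.227) or without promoter peaks (0.318-fold, adjusted p = 0.232).

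The 57 genes of the 4 cortical cell type lists were more accessible than the 43 genes of liver, skeletal muscle, pancreas and gut. Cortical genes had 0.615 regions per 10 kb (SD over genes 0.653) and the genes of the other organs 0.270 (SD 0.334), a difference of 0.345 (two-sided permutation test over genes, p = 0.00126, adjusted p = 0.00252). Promoter peaks in both mice were present at 35 of 57 cortical genes (61.4%) and at 5 of 43 of the others (11.6%). Those 5 were the liver gene Apob (3.06 and 1.42), the muscle genes Actn3 (7.03 and 4.78, a peak shared with Zdhhc24), Ckm (4.79 and 1.56) and Pygm (1.56 and 1.14), and the elastase gene Cela1 (3.46 and 1.39). The liver genes Ahsg, Alb and Apoa1, the muscle genes Acta1, Mb and Myh1 and the gut and pancreas genes Cdx1, Cdx2 and Cpa1 had none. The pooled promoter shares were not matched on promoter CpG content. Random lists matched on it had mean shares of 54.6% to 75.3% for the 4 cortical lists and 32.2% to 42.6% for lists of the other organs. The 61.4% of cortical genes lay inside the first range, and the 11.6% of the others lay below the second. Taken singly, excitatory neuron genes exceeded the other organs by 0.721 regions per 10 kb (adjusted p = 0.00064 over 8 permutation tests), astrocyte genes by 0.307 and oligodendrocyte genes by 0.293 (both adjusted p = 0.0288), and interneuron genes by 0.0336 (adjusted p = 0.754). With 50 kb flanks the joint difference was 0.0967 and was not past the threshold (permutation p = 0.104). It was 0.587 without replicate 1, 0.706 without replicate 2, 0.195 without promoter peaks and 0.218 above the median height.

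Cortical genes were not shown to differ in density from genes of other brain regions. The 31 genes of striatum, hypothalamus, midbrain, hindbrain and cerebellum had 0.498 regions per 10 kb (SD over genes 0.615), 0.117 fewer than the cortical genes (two-sided permutation test over genes, p = 0.421). Excitatory neuron genes alone exceeded them by 0.493, which missed the threshold after adjustment (permutation p = 0.0367, adjusted p = 0.0735). Of 10 striatal genes 6 had a promoter peak in both mice (adjusted permutation p = 0.243), including the signalling gene Rgs9 (4.86 and 2.82) and the dopamine receptor gene Drd1 (4.11 and 1.72), but not Adora2a (peak in replicate 1 only), Drd2 or Isl1. Of 21 genes of the other regions 4 had one, fewer than random lists (adjusted permutation p = 0.001): the neuropeptide gene Hcrt (5.47 and 3.09), Agrp (4.32 and 3.37, a peak at the start of Ctcf), Pax5 (1.79 and 0.847) and Tph2 (1.39 and 0.662), the last named only after its value was seen, while Avp, Barhl1 and En1 had none. Their densities of 0.626 and 0.437 did not pass the threshold (adjusted permutation p = 0.665 and 0.713). In the longer lists all 10 striatal and 8 of the other regional promoters were open, and there were 7 of the latter without replicate 1 (density 0.746, 1.17-fold random, from below it) and 2 with a 500 bp window or above the median height. The joint difference of 0.117 was 0.198 without replicate 1, 0.385 without replicate 2, 0.0333 without promoter peaks and 0.00971 above the median height, none past the threshold.

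Hox and olfactory receptor genes were poor in accessible regions. Of 39 Hox genes, which pattern the body axis behind the forebrain, 2 had a promoter peak in both mice (adjusted permutation p = 0.001). They were Hoxa7 (6:52214491-52221854, 3.57 and 1.92) and Hoxa10 (1.06 and 0.684), but not Hoxa11 (peak in replicate 2 only) or Hoxa13. All 39 are counted in the density that follows. The Hox density was 0.205 against 0.567 in random lists (adjusted permutation p = 0.00133). Of 1134 olfactory receptor genes 10 had a promoter peak (adjusted permutation p = 0.001), and their density was 0.0326 against 0.590 (adjusted p = 0.00133). Before adjustment these 4 p-values were each 2e-04, the smallest that 10000 lists can give. Liver promoters (1 of 15, adjusted permutation p = 0.0467) and pancreas and gut promoters (1 of 14, adjusted p = 0.001) were open less often than in random lists, and muscle promoters were not past the threshold (3 of 14, adjusted p = 0.243). Densities were 0.299 for liver (adjusted permutation p = 0.128), 0.290 for muscle (adjusted p = 0.14) and 0.220 for pancreas and gut (adjusted p = 0.04). The Hox density was 0.690 without replicate 2 (adjusted permutation p = 0.648) and 0.357 without replicate 1, and its call was lost without promoter peaks (0.672-fold random, adjusted p = 0.431), with 4 to 6 open promoters in single libraries or the longer lists, where olfactory receptor promoters numbered up to 17 (1 above the median height). The pancreas and gut density call, at 0.405-fold random, was lost without replicate 2 (0.4197-fold, adjusted permutation p = 0.076), with 50 kb flanks (0.729-fold, adjusted p = 0.377) and without promoter peaks (0.914-fold, adjusted p = 0.959), the liver promoter call above the median height (0.266-fold, adjusted p = 0.177), and muscle promoters passed it with a 500 bp window (1 open, adjusted p = 0.0262) and numbered 6 in the longer lists, with a muscle density of 0.509 without replicate 1.

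Activity-dependent, synaptic and housekeeping genes were rich in accessible regions. The 15 immediate early genes, which neurons induce on stimulation, had 1.97 regions per 10 kb, 3.77-fold above random lists (adjusted permutation p = 0.00133), and all 15 had a promoter peak (adjusted p = 0.190). Egr1 (18:34859823-34864984, 9.24 and 5.33), Arc (15:74669083-74672570, 9.005 and 4.20) and Homer1 (13:93299635-93405129, 7.54 and 5.42) had the highest. The 17 synaptic genes had 0.684 regions per 10 kb, 2.10-fold above random (adjusted permutation p = 0.0016), and 17 open promoters (adjusted p = 0.0255), led by the vesicle protein gene Vamp2 (8.71 and 3.67), with Pclo at 4.67 and 2.87. The 16 housekeeping genes had 1.16 (2.06-fold, adjusted permutation p = 0.004) and 16 open promoters (adjusted p = 0.0571), with Rplp0 (19.1 and 10.1), Ppia (14.2 and 6.08) and Actb (9.92 and 6.74) highest. Without promoter peaks the housekeeping density was no longer past the threshold (0.272, 1.59-fold random, adjusted permutation p = 0.328), and its promoter count passed it above the median height (adjusted p = 0.012) and with a 500 bp window (adjusted p = 0.0396). Synaptic densities in single libraries were 1.18 in each, and the synaptic promoter call was lost in the longer lists, where all 17 were still open (1.22-fold random, adjusted permutation p = 0.0664).

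**Figure D2:**
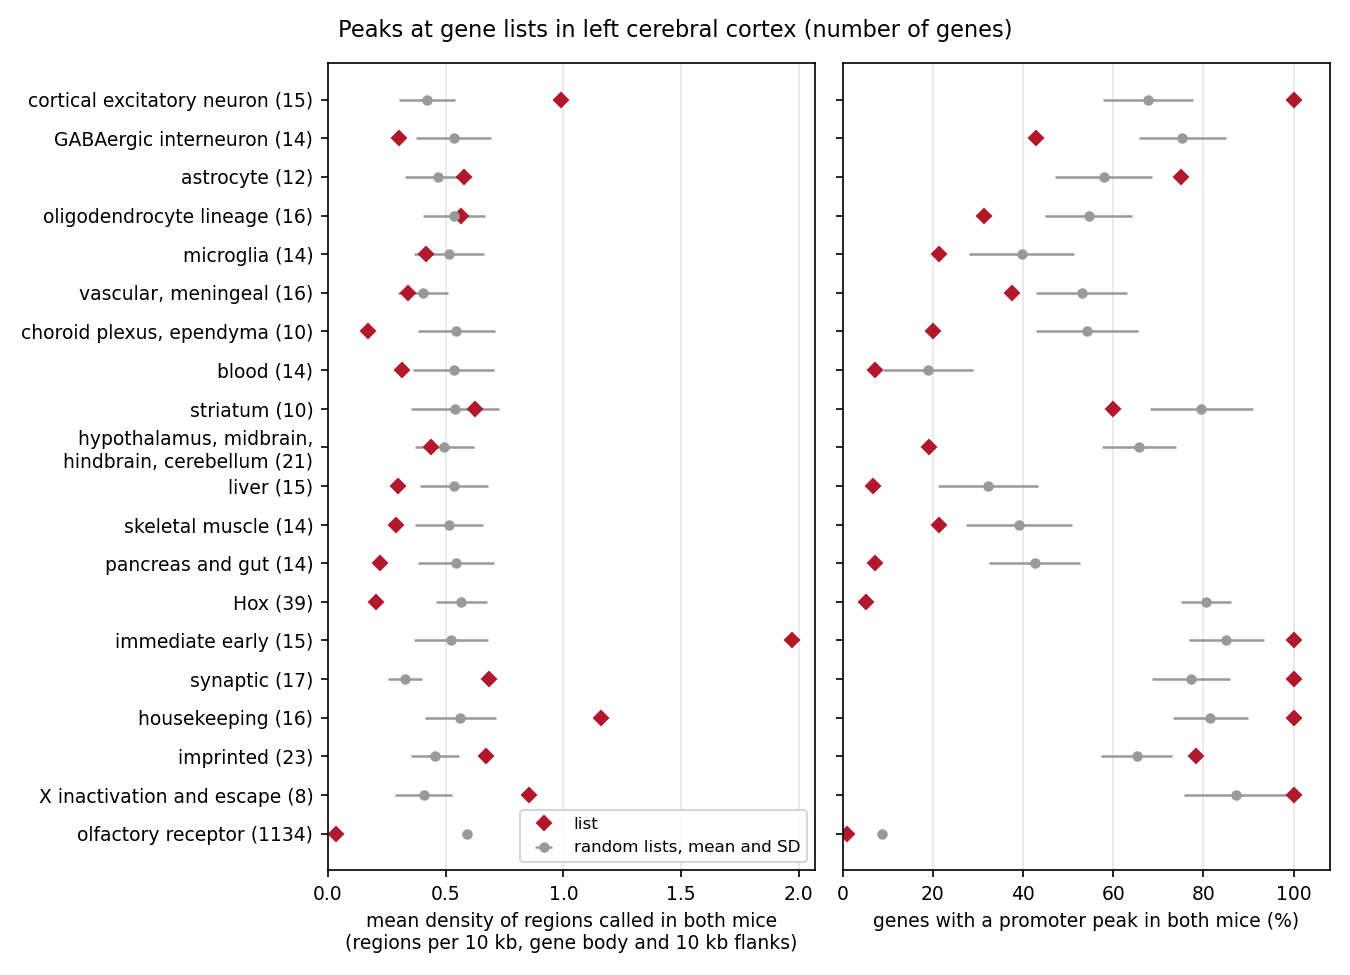
Accessible regions at 20 gene lists, with the number of genes in brackets, against 10000 random lists (grey, mean and SD). The left axis gives regions called in both mice per 10 kb and the right axis the percent of genes with a promoter peak in both mice, and immediate early genes reach 1.97 regions per 10 kb where olfactory receptor genes have 0.0326.

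Imprinted genes and X-linked genes of dosage compensation had mostly open promoters. Of 23 imprinted genes, which are expressed from 1 parental copy, 18 had a promoter peak in both mice (adjusted permutation p = 0.229), with Inpp5f (3.79 and 3.88), Kcnq1ot1 (3.69 and 2.86) and Usp29 (3.55 and 2.91, a peak shared with Peg3) highest and Dlk1 (peak in replicate 2 only), H19 and Igf2 without. Their density of 0.672 was not past the threshold (adjusted permutation p = 0.107). All 8 genes of X inactivation and escape from it had a promoter peak (adjusted p = 0.639), with the demethylase genes Kdm6a (11.8 and 8.98) and Kdm5c (6.89 and 5.21) and the helicase gene Ddx3x (6.96 and 4.21) highest, and their density of 0.855 was 2.10-fold above random (adjusted p = 0.00743, permutation of lists). That call was lost with 50 kb flanks (1.47-fold, adjusted permutation p = 0.189). It was also lost without replicate 1 (1.76-fold, adjusted permutation p = 0.0884) and without replicate 2 (1.72-fold, adjusted permutation p = 0.157). The imprinted density passed the threshold without replicate 1 (1.06, adjusted permutation p = 0.0185).

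The genes with the most regions were long. Among protein-coding models, Gm20388 (8:119910841-124345722) held 237 regions and Fgfr2 (7:130162451-133123350) 88, over annotated spans of 4435 and 2961 kb. Camta1 held 39, Gse1 36, Auts2 and Kalrn 34 each, Asic2 29, Cdh13 27, Gm37240 26 and Nav2 25. Regions were counted over the whole annotated span and its flanks, including any that lie at other genes within it. Gse1 (8:120228456-120581390) lies inside the span of Gm20388, so its regions count for both. The highest promoter peak was shared by Hjurp and Trpm8 (1:88262471-88277633 and 1:88277661-88389293), with heights of 23.9 in replicate 1 and 16.9 in replicate 2. Means of the mice, which rank the genes, mix the unstated scales of the libraries. Gm21887 on X followed with a mean of 16.3, 1700123O20Rik and Acin1 with a shared peak of 15.9, Zswim1 with 15.3, Ccdc66 with 15.1, the cilia gene Rsph1 with 14.7, and 4930535I16Rik and Rragc with a shared peak of 14.6.

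Footprints, short protected stretches inside accessible DNA, sat on the recognition sequence of the insulator protein CTCF more than on any other of 26 motifs in each mouse when set against the flanks. Inside peaks, 95.3% ± 1.59 of CTCF matches (SD, n = 2 mice) had a footprint over their centre, 96.5% of 4712 in replicate 1 (Wilson 95% interval 95.9 to 96.9) and 94.2% of 4211 in replicate 2 (93.5 to 94.9). Positions 50 bp to each side were covered in 9.81%, a ratio of 10.6 ± 4.20 (SD, n = 2 mice). Matches of NFI followed with 84.8% from 46 matches per mouse, RFX with 69.5%, the activity-induced EGR factors with 74.7%, NRF1 with 95.9%, CRE with 76.6% and the neuronal NEUROD factors with 40.3%. KLF_SP (63.7%), ZBTB33 (68.8%), USF (49.99%), YY1 (55.6%), ETS (38.9%) and the neuronal repressor REST (43.8% ± 15.7) were also above their flanks, and REST stood at 54.9% of 82 matches in replicate 1 and 32.7% of 52 in replicate 2, with counting intervals of 44.1 to 65.2 and 21.5 to 46.2. The difference between the mice was not tested. Of the control motifs of other tissues, MYOD was covered at 21.4%, HNF4 at 18.96% and GATA at 9.05%, with ratios of 1.24, 0.834 and 0.508, and HNF1 had no match. AP1, SRF, PU1, SOX, TEAD, ROR, MEF2 and POU were all covered less than their flanks, and the share for GR was 19.6% with a ratio of 1.19. In a test chosen after the data were seen, distal peaks with a CTCF match were lower in replicate 2, with a mean centred log2 ratio of -0.51 (SD over peaks 0.49, 3504 peaks) against 0.01 (SD 0.52) for the 23506 without a match. The gap was -0.35 against distal peaks of the same height and -0.15 against those of the same height and width. Of the peaks without a match, 23.5% were near matches, 1 position off the consensus. With these left out the gaps were -0.48 and -0.23.

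**Figure D3:**
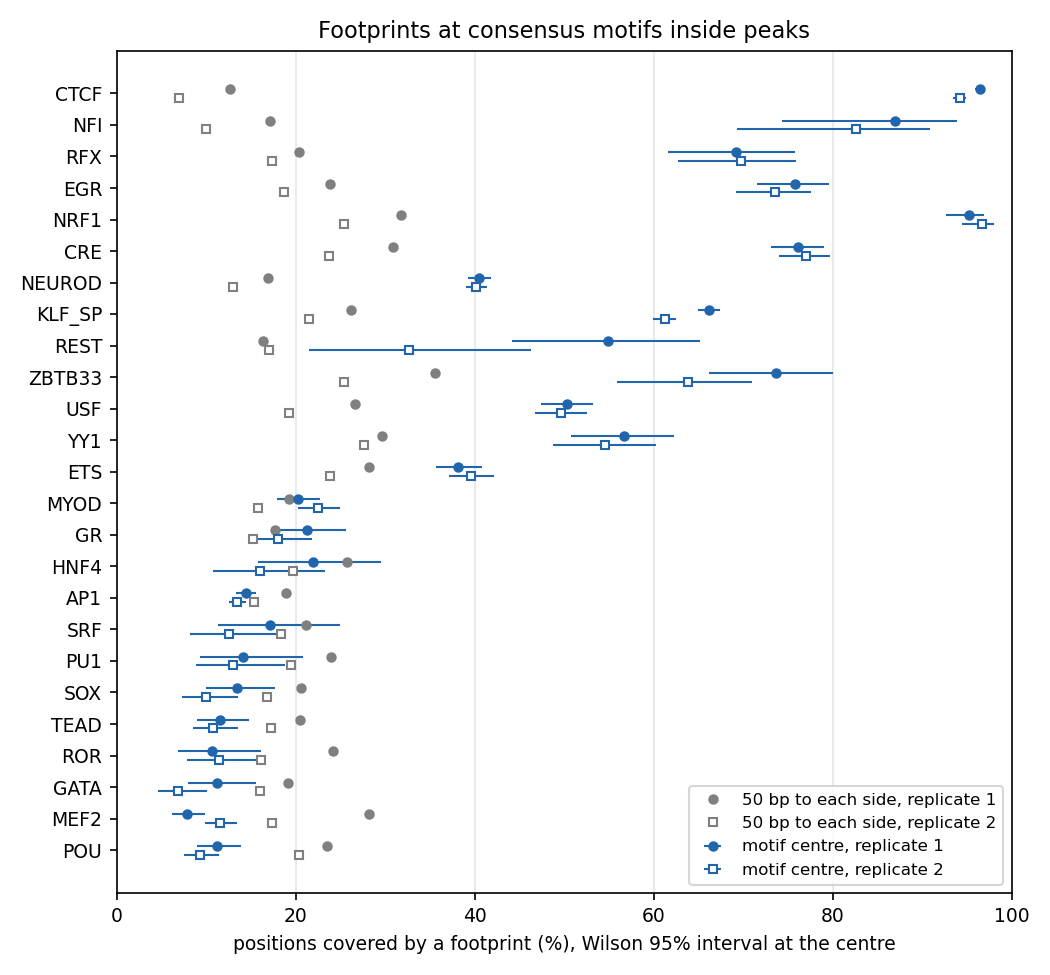
Percent of motif centres inside peaks that a footprint covered (blue, with Wilson 95% intervals) and of positions 50 bp to each side (grey), per replicate, for the 25 motifs with matches. CTCF combined 95.3% at the centre with 9.81% at the flanks, whereas GATA had 9.05% at the centre.

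Footprints recurred in the other mouse more often than random placement gives. Replicate 1 had 318728 footprints with a median width of 10 bp and replicate 2 had 317176 with 9 bp, and 86.6% and 87.0% of peaks held at least 1. Not all deposited footprints lay in called regions. In replicate 1, 63.8% overlapped a peak and 87.0% a region of the longer list, and in replicate 2, 63.9% and 86.5%. Of the footprints, 44.2% in replicate 1 and 46.2% in replicate 2 overlapped one of the other mouse. The mean was 45.2% ± 1.40 (SD over the 2 directions of 1 comparison, not a spread between mice). Inside peaks the shares were 54.5% and 57.6%, against 29.3% and 29.5% for footprints placed at random within the same peaks, which never exceeded 29.8% in 100 placements.

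The X chromosome carried few accessible regions for its length. There were 10.1 peaks per Mb on X in replicate 1 and 9.79 in replicate 2, 0.346 ± 0.01003 (SD, n = 2 mice) of the median autosome, which had 28.7 and 28.9. The sparsest autosome, chromosome 3, had 20.8 and 21.5, and the densest, chromosome 11, had 43.3 and 42.1. Peaks on X were also lower, with a median height of 0.833 against 1.19 on autosomes in replicate 1 and 0.668 against 0.914 in replicate 2. The Y chromosome, which female mice lack, held 23 peaks in replicate 1 and 17 in replicate 2, and 27 of these 40 have a near-identical copy on another chromosome.

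The broader set of accessible regions was of like size in the animals. The longer lists held 120027 regions over 25.8 Mb in replicate 1 and 120701 over 28.4 Mb in replicate 2, a mean of 27.1 Mb ± 1.77 (SD, n = 2 mice). They overlapped 98.3% and 98.2% of the peaks of the same mouse.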

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

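The tests of peaks found in 1 mouse only and of male DNA were chosen only after the result was seen.

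Many peaks called in 1 mouse alone had signal in the other mouse's rate data, which the comparisons of peaks do not use. Of 17566 peaks of replicate 1 without a peak in replicate 2, 10595 (60.3%) held positions under a rate of 0.05 there, against a mean of 457.6 in 20 random placements. Of 17773 peaks of replicate 2 without a peak in replicate 1, 12255 (69.0%) did, against 435.2. Under the rate of 0.001 that every peak of the shorter lists meets, the counts were 3042 (17.3%) and 2465 (13.9%).

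Peaks on Y stand out because female mice have no Y chromosome: of 40, 27 (67.5%, Wilson 95% interval 52.0 to 79.9; 13 of 23 in replicate 1, 14 of 17 in replicate 2) had a copy of at least 95% identity over at least 90% of their length on another chromosome, against 41 of 200 random Y windows (20.5%, 15.5 to 26.6), so sequence shared with X or autosomes is a candidate explanation for those 27. Places called in both mice are counted once per mouse and many peaks lie close together, so the interval of the 40 is too narrow. The 13 peaks without such a copy all lie in Y:90717641-90744820 and stay open, among them the highest of replicate 1 (Y:90744581-90744820, 9.50), although the peak of replicate 2 at nearly that place (3.98) has one on X. The reverse holds at Y:90718581-90719000 in replicate 1, with a copy on X of 95.4% identity. The overlapping peak of replicate 2 (Y:90718721-90719040) has none. At both places the call turns on the exact ends of the peak, so these peaks are not shown to lack shared sequence. In the longer list of replicate 2, 3 of the 4 Y genes with X copies (Kdm5d, Uty, Ddx3y, Eif2s3y) had a promoter peak: Uty (Y:1245728-1245838, height 0.0785), Ddx3y (Y:1286493-1286600, 0.0617) and Eif2s3y (Y:1010461-1010640, 0.118), where 10000 random placements of its 45 Y peaks hit at most 2. The placements ran evenly over all of Y, where 84856465 of 88124698 assembled bases are repeat sequence. They do not show what placement in the unique part alone would give. Reads of the X copies placed on Y are argued against, since 0 of the 3 genes have a peak with such a copy, and a trace of male DNA in replicate 2 may account for these small peaks, whose heights were 0.874% to 3.63% of those at the X copies. In replicate 1, 0 of 4 genes had a peak while all 4 X copies had one. A trace too small to be called as a peak would look the same, so male DNA in replicate 1 cannot be excluded. No biological explanation was tested.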

How the results depend on the processing

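The tests against the other mouse's longer list or listed positions, those of promoter peaks in the longer lists and those of single lists were chosen only after the result was seen. The share of peaks in both mice (74.5%) was 60.5% with 50% reciprocal overlap, 84.9% above the median height and 71.8% in the longer lists, and 87.3%, 78.4% and 91.0% of peaks met the other mouse's longer list or its positions under a rate of 0.001 or 0.05. Spearman's rho of heights was 0.833 above the median height and 0.901 with reciprocal overlap. The promoter share was 32.0% with a 500 bp window, 45.9% with 2 kb, 35.4% with protein-coding starts, 52.0% above the median height and 38.4% to 40.2% in single libraries. The cortical excess over liver, muscle, pancreas and gut lost its call with 50 kb flanks (0.0967, permutation p = 0.104, the cause was not tested). Under the other 5 settings it passed (permutation p = 7e-05 to 0.0101), with 0.587 to 0.706 in single libraries, 0.195 without promoter peaks and 0.218 above the median height. The comparison with other brain regions passed under none of 6 settings (permutation p = 0.0838 to 0.923), with 0.198 to 0.385 in single libraries. Cortical genes with a promoter peak numbered 25 to 42 under 5 settings, and 38 to 41 in single libraries. Of footprints, 31.5% were shared with 50% reciprocal overlap and 60.5% inside shared peaks, and high-scoring footprints could not be tried because the score is constant. CTCF matches were covered in 97.6% with a 1 bp overlap, 88.9% in the longer lists, 97.8% above the median height and 94.2% to 96.5% in single libraries. The density ratio of X was 0.240 above the median height, 0.273 away from starts and 0.339 to 0.353 in single libraries. Longer lists covered 25.8 to 28.4 Mb in single libraries and positions under a rate of 0.001 covered 23.8 Mb. For single lists, 172 values stayed on their side of the threshold, 18 lost the call and 10 gained it, and no called value changed direction. For the values that moved, the cause was not tested. Depth in reads is unknown, so what it limits could not be measured.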

Other observations

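All tests in this part were chosen only after the result was seen.

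Promoters with many CpG sites were open most often. Of protein-coding genes, 13401 of 21938 (61.1%) had a promoter peak in both mice. The share was 7.36% in the quintile of lowest promoter CpG content, then 30.8%, 78.1%, 92.2% and 94.9%. Among noncoding genes it was 49.9% for processed transcripts, 32.7% for antisense genes, 16.7% of 5854 lincRNA genes and 12.1% for miRNA genes. Processed pseudogenes, copies of transcripts without their promoters, had one in 2.04% of 9940 cases, and unprocessed pseudogenes in 1.06%.

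CTCF sequences were enriched at distal and at promoter peaks. In 200 bp windows at 27978 distal peaks they were present in 12.3% against 0.0929% of GC-matched flanks (133-fold), and at 19957 promoter peaks in 2.31% against 0.13% (17.8-fold). At distal peaks EGR was 5.06-fold and CRE 3.49-fold above flanks, AP1 was present in 8.35% against 3.38% and the neuronal NEUROD factors in 12.2% against 5.31%, while GATA was at 0.580-fold. At promoter peaks USF was 13.9-fold, ETS 7.49-fold and CRE 5.55-fold above flanks, KLF_SP was present in 11.9% against 6.33%, and NEUROD was at 0.800-fold. Too few flanks held NRF1, YY1, ZBTB33 or RFX for a fold, with 261, 158, 119 and 51 promoter windows against 4, 7, 0 and 0 flanks.

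Distal peaks with a CTCF match were lower in replicate 2, with a mean centred log2 ratio of -0.51 (3504 peaks) against 0.01 without a match, and against peaks of the same height CTCF alone of 18 motifs had a negative difference, while 12 others passed the threshold the other way (RFX 0.23, PU1 0.21, MEF2 0.18, NEUROD 0.14). For the other motifs, peaks with a CTCF match or near match (1 position off) were left out, while the controls of CTCF kept near matches. Sites further off the consensus could remain in the controls of the other motifs. Those controls were matched on height only, not on width, and the threshold runs over peaks of 1 pair of libraries. The positive differences therefore cannot be assigned to those motifs. Heights compressed in replicate 2 and GC content of the peaks are argued against as the whole cause of the CTCF difference. It was -0.35 from 1000 random sets matched on height and -0.32 from sets matched on height and GC. Peak width as the whole cause left -0.23 once near matches were left out, by a criterion set after its values were seen. Height alone left -0.48 with the same peaks left out. With near matches kept, adding width to height took the difference from -0.35 to -0.15, the smallest of 8 matchings tried, so width may account for over 50% of what height leaves. Digestion or fragment selection is untested and stays open. No biological explanation was tested, because the mice form 1 group.

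Another mixture of cell types in the 2 pieces of cortex might move peak heights at marker genes together. Against random peaks matched on height, promoter class and CTCF match, none of 18 gene lists stood apart after adjustment, and before it 2 did (synaptic and immediate early genes). Among 7 cell type lists the smallest adjusted permutation p was 0.312, for interneurons (difference -0.20, 14 peaks). These 2 differed by 0.12 and 0.11 (both adjusted permutation p = 0.0918). With so few peaks per list, a different mixture cannot be excluded.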
